A study of Mus musculus with 16 samples.

How the data were processed

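RNA expression was measured on 16 spotted oligonucleotide arrays, 1 hybridisation each, in 5 groups: control (3), microfluidic (3), conventional (3), single_cell (4) and explant (3). Groups and preparation details were taken from the labels. The 16 scanner files hold, per the file headers and column names, the raw foreground and local background intensity of each of 25344 spots at 1 wavelength, written by the Mapix software (versions 2.3.0, 2.2.4, 2.4.4 and 2.5.1); the 3 conventional files have no header block. This deposited intensity is neither background-subtracted nor normalized, and stops at 65535. The spot marks (bad, not found) of the deposited files are on no measurement scale. The deposited signal values of the series table are on a linear scale, were made by the authors in a way the labels do not state, and were used only as an alternative.

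Probe names came from the platform table (20370 probes with 1 symbol) and current RefSeq symbols (21042 probes); 285 probes with conflicting names are not named. Spots that the files name Actb carry an accession that belongs to Lrrc58, so Actb is not reported. In the 3 files without a header, 18 gene names had been turned into dates or numbers, so names were taken from another array, whose spots are in the same order. Spots marked bad were left out unless saturated. Intensities were background-corrected by normexp (offset 50) and quantile-normalized over all 16 arrays in limma 3.58.1 under R 4.3.3, then taken to log2. A probe was called detected where the foreground median was above the background median plus 2 background SD. For conventional 1, whose file has no background SD, the limit was the 95th percentile of blank spots.

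Control, microfluidic, conventional and explant arrays were compared in 4 pairs by limma (two-sided, each pair with its own spread) over probes detected on all arrays of at least 1 of the groups, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Where all arrays of 1 group were undetected or saturated, folds are given as lower bounds: an undetected probe was put at the lowest detected intensity of its array. A probe saturated on only some arrays of a group is given as fitted. In that case "lower" and "higher" stand for probes that passed the test. Correlations and shares were compared by exact permutation. Single cells were described without tests, with list medians set against 10000 random lists matched on expression. The deposited data give no cell's animal, and replicate numbers do not pair samples across groups.

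Gene lists were fixed before the data were examined, as were the comparisons, the tests and most alternatives: CGE and ganglionic eminence identity; immature and migrating neuron; neural progenitor; cell cycle; pallial and glutamatergic lineage; mature neuron and synapse; oligodendrocyte and myelin; astrocyte; microglia and macrophage; endothelium and pericyte; erythroid cell; cytoplasmic ribosomal protein; nuclear-encoded oxidative phosphorylation; replication-dependent histone; housekeeping; immediate early and stress response. They were tested with camera at a preset correlation of 0.01, and again with the correlation estimated, adjusted over the lists of a comparison. Camera asks whether a list moved differently from the other tested probes. Named genes follow a rule fixed at the same time: in each test the 8 largest rises and 8 largest falls that passed without overlap of the groups and have a plain symbol, up to 3 members of each list with the smallest p, and a set of anchor genes (Gapdh, Tubb3, Dcx, Sox11, Dlx1, Dlx2, Dlx5, Gad1, Gad2, Mki67, Mbp, Snap25, Camk2a) wherever measured. For cells these were the 8 highest and 8 lowest with all cells on 1 side, 4 genes per cell with the largest excess over the other cells, and list members with the largest differences; not every gene that the rule allows is printed. A gene with several probes is represented by its brightest.

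Alternatives were no background correction, median centring, quantile normalization within 2 groups, the deposited signal values, no dim-probe filter, a trend or a common spread in limma, the replicate number as a block, other detection limits, all probes, rank correlation, and each array left out. Alternatives added after seeing the data were probes detected in both groups, leaving out saturated spots marked bad, filling the missing background SD, and further alternatives for the lists. A block for scan session could not be fitted, since each session holds 1 group. The test was tried on simulated data: with shifts of 4 log2 units added to 66 probes, limma recovered 84.8% for microfluidic against control, 34.8% for conventional against control, 60.6% for microfluidic against conventional and 95.5% for explant against control, and with shifts of 1 log2 unit 0% to 4.48%. The simulation shifted few probes, with noise independent between probes, whereas a large share passed in the real comparisons. Adjustment was therefore stricter in the simulation, and these shares do not give the power of the tests reported below. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.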

Results

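The series tests a microfluidic rotary mixer built to measure the transcripts of individual cells. Gene expression was read on 16 spotted mouse arrays, each hybridised with 1 Cy5-labelled sample and carrying 24109 gene probes. The 3 control arrays received 15 µg of unamplified adult forebrain RNA. For the 3 microfluidic arrays, 10 pg of adult forebrain RNA was reverse-transcribed in 7 nL inside the mixer, and for the 3 conventional arrays the same amount was reverse-transcribed in 10 µL in a tube. Both were then amplified by 40 cycles of template-switching PCR, in which the reverse transcriptase adds a primer site where it reaches the end of the RNA. The 4 single-cell arrays hold individual cells from the caudal ganglionic eminence (CGE) at embryonic day 14, a forebrain region that gives rise to cortical interneurons, carried through the mixer and 40 cycles, with reverse transcription for 25 min instead of the 20 min of the 10 pg reactions. The 3 explant arrays received 5 µg of unamplified RNA from embryonic day 14 tissue, named CGE in the sample labels and telencephalon in the extraction protocol.

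Signal over background differed between the groups. The share of probes detected was 66.5% ± 2.51 on the control arrays (SD, n = 3), 47.6% ± 8.61 on the microfluidic arrays (n = 3), 39.8% ± 11.2 on the single-cell arrays (n = 4) and 23.7% ± 7.69 on the explant arrays (n = 3). On the conventional arrays it was 43.8%, 3.25% and 5.76%, the first of these by a rule based on blank spots because that file holds no background SD; with the mean SD of the other conventional arrays filled in it was 4.46%, and the group mean 4.49% ± 1.26. Median intensity over background was 3835 on the control arrays, 1359 on the microfluidic, 203 on the conventional, 1336 on the single-cell and 823 on the explant arrays. Spots for Gapdh, a glycolytic enzyme printed many times on each array, had median net intensities of 64169 to 64256 in control, 8199 to 27397 in microfluidic, 375 to 1975 in conventional, 4485 to 56156 in single-cell and 12030 to 16554 in explant arrays. Between 479 and 672 probes were saturated on a control array, 569 to 906 on a microfluidic, 40 to 61 on a conventional, 432 to 941 on a single-cell and 127 to 193 on an explant array. Wherever the file headers give a scan session, each session holds arrays of 1 group only, so scan batch and group cannot be told apart. Cells 1 to 3 share 1 session and cell 4 was scanned in another. The explant arrays also come from another slide print series than all other arrays with a header. The number of arrays, 3 or 4 in a group, limits the precision of every value.

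**Figure D1:**
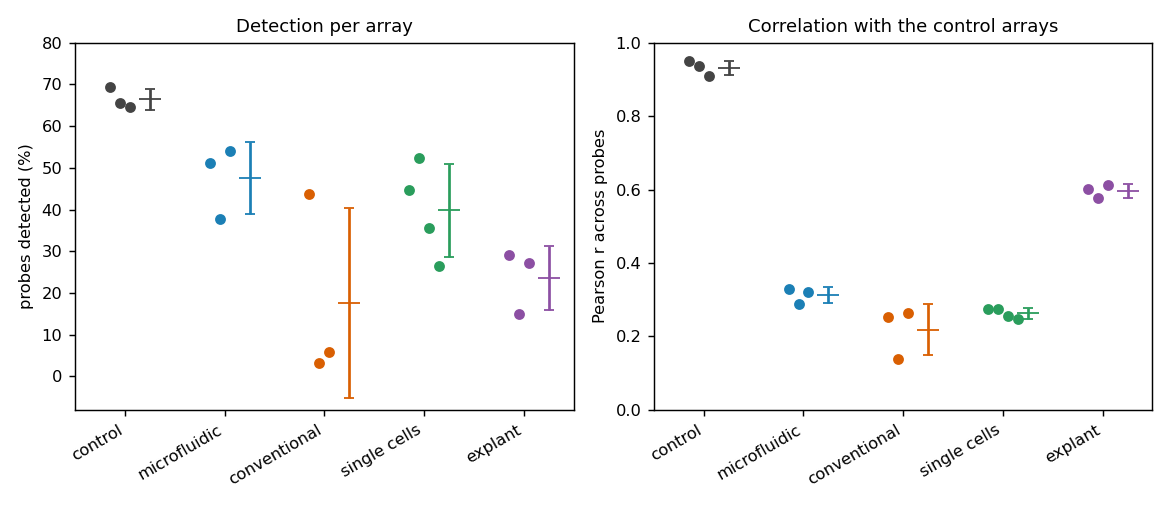
Left, percentage of gene probes detected above local background on each array; right, Pearson r across probes between each array and the mean of the control arrays (for a control array, the other control arrays). Points are arrays, bars the mean and SD of a group; the conventional arrays lie at 43.8%, 3.25% and 5.76% in the left panel, and their SD reaches below 0.

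Microfluidic arrays were compared with control arrays to ask how a 10 pg reaction in the mixer represents the transcripts of adult forebrain. Among the genes with the largest fitted falls, Ppp2r1a and Ppp2ca, the scaffold and catalytic subunits of protein phosphatase 2A, were at least 47.2-fold and 29.3-fold lower (adjusted p = 4.68e-05 and 1.49e-04). The amyloid precursor relative Aplp1 was at least 43.2-fold lower, the glycolytic gene Pkm at least 32.9-fold and the neuronal secreted protein Nell2 at least 29.7-fold. Dlg4, which encodes a scaffold of the postsynaptic density, was at least 39.8-fold lower (n = 3 and 3; adjusted p = 4.53e-04). The largest fitted rises among genes with a plain symbol belonged to Scn2b, a sodium channel subunit (at least 68.3-fold higher), Slc24a5, a cation exchanger (72.5-fold), Plaa (58.5-fold), Schip1 (45-fold), Rdh13, a retinol dehydrogenase (40.9-fold), Lrrc8a, an anion channel subunit (40.2-fold), Ces2e, a carboxylesterase (39.9-fold), and Tut7, a uridylyltransferase (27.4-fold), each value again a lower bound. A further Tut7 probe gave a log2 difference of -0.08. In each of these 14 genes the 3 arrays of 1 group lay apart from the 3 of the other.

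Markers of mature neurons fell together: 25 of 34 tested members of the mature neuron and synapse list fell and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 8.19e-06, or adjusted p = 0.0707 with an estimated correlation, 2.97e-08 to 0.0707 over the alternatives). Among them, beta-synuclein (Sncb) was at least 47.0-fold lower, synaptophysin (Syp) at least 21.7-fold and the opioid precursor Penk at least 9.30-fold. In the astrocyte list 10 of 16 members fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.0418, and adjusted p = 0.247 with an estimated correlation), with the filament gene Gfap at least 22.6-fold and the glutamate transporter Slc1a2 at least 8.67-fold lower, while the gap junction gene Gja1 was at least 5.70-fold higher. Of 62 genes of nuclear-encoded oxidative phosphorylation, 34 fell and 6 rose (35 and 6 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.122 with an estimated correlation). Uqcrh and Sdhc of that list were at least 7.72-fold and 12.7-fold lower. The other 13 lists had adjusted p from 0.0561 to 0.899. They included cytoplasmic ribosomal proteins, where 11 members rose, led by Rps28 (at least 20.8-fold higher), and 25 of 68 fell, led by Rpl41 (-5.27 ± 0.34 log2 units; SE, n = 3 and 3). Of the cell cycle list 8 members rose and 3 of 21 fell, and of the CGE list 2 rose and 10 of 21 fell.

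Genes named in advance moved both ways. The myelin protein gene Mbp was at least 25.6-fold lower, the synaptic gene Snap25 at least 12.5-fold, the proliferation marker Mki67 at least 4.5-fold and Gapdh at least 2.96-fold; with median centring the Gapdh difference was -0.41 and no longer passed. Camk2a, a synaptic kinase, was at least 33.1-fold lower by its brighter probe, whereas a further probe gave -0.45. The GABA-synthesis genes Gad1 and Gad2 fell by 2.76 ± 0.43 and 2.79 ± 0.59, although a further Gad2 probe gave -0.49. Dcx and Tubb3, both expressed in young neurons, rose by 1.97 ± 0.26 and 1.28 ± 0.29. The interneuron transcription factor gene Dlx2 had a log2 difference of -1.0 ± 0.31 (adjusted p = 0.0292) that turned to 0.25 with median centring, and Dlx1 and Sox11 had differences of 0.78 ± 0.73 and 0.11 ± 0.34.

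By limma, 8932 of 14844 tested probes changed, 3725 higher and 5207 lower on the microfluidic arrays, and 10075 had no overlap between the groups, against 10% by chance over unselected probes. Choosing probes by detection on all arrays of 1 group raises that share, here and in the other comparisons, so these counts are descriptions. Of the changed probes, 822 higher and 2727 lower probes were not detected on any array of the dimmer group. The median log2 difference of all tested probes was -0.40, and -0.77 to -0.14 under the other scalings. Among probes detected on all 6 arrays 2898 changed, of which 66.3% were higher. The median, mean and test of 5 lists differed in sign: neural progenitor, cell cycle, pallial and glutamatergic lineage, replication-dependent histone, and immediate early and stress response. The astrocyte call was also lost with median centring, with the deposited signal values, without microfluidic 2 and without control 3 (adjusted p 0.00278 to 0.247 over the 15 alternatives), and the oxidative phosphorylation call among probes detected on all 6 arrays (0.985; range 7.14e-04 to 0.985).

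Conventional arrays were compared with the same control arrays to ask the question for a tube reaction. The genes named for the largest fitted falls were not detected on any conventional array, where the detection limit is high, so that the bounds are small. The apoptosis inhibitor Faim2 was at least 7.56-fold lower (adjusted p = 7.00e-04), Gdf7 at least 7.26-fold, Ppp2r1a at least 6.71-fold, Vwa3a at least 5.53-fold, the proton pump gene Atp6v1b2 at least 5.31-fold, Riiad1 at least 4.73-fold, the neuronal RNA-binding gene Elavl4 at least 2.90-fold and the dendritic microtubule gene Map2 at least 2.84-fold. Genes at background on the control arrays were bright on all 3 conventional arrays: Tmem200a was at least 51.8-fold higher, the membrane adaptor Gapt 48.8-fold, the defensin Defb7 48.4-fold, the condensin subunit Smc2 46.4-fold, the transcription factor Nfe2l1 44.8-fold and the glycolytic regulator Pfkfb4 32.7-fold. Upf3b, of nonsense-mediated decay, rose by 5.73 ± 0.46 (SE, n = 3 and 3).

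In the mature neuron and synapse list 25 of 34 members fell and 0 rose (26 and 0 adjusted over the list alone; camera adjusted p = 7.88e-07, or adjusted p = 0.0522 with an estimated correlation, 6.06e-11 to 0.0522 over the alternatives). They included Dlg4 (at least 6.05-fold lower), the syntaxin gene Stx1a (5.90-fold) and Snap25 (3.81-fold). Astrocyte genes fell in 10 of 16 and rose in 0 cases (12 and 0 adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.167 with an estimated correlation, 2.91e-05 to 0.167 over the alternatives), with Gfap at least 3.21-fold and the glutamine synthetase gene Glul at least 1.91-fold lower. Housekeeping genes fell in 11 of 18 and rose in 0 cases (11 and 0 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.167 with an estimated correlation, 1.38e-04 to 0.167 over the alternatives), among them Aldoa (at least 3.81-fold lower), Gapdh (at least 2.12-fold) and the ubiquitin gene Ubb (at least 4.26-fold). The other 13 lists had adjusted p from 0.0579 to 0.992, the lowest for neural progenitor genes, of which 4 of 14 rose and 4 fell. Mki67 and the mitotic kinesin Kif11 rose by 3.15 ± 0.46 and 3.15 ± 0.61, the pericyte receptor Pdgfrb by 5.18 ± 0.55 and the transcription factor Gli3 by 3.24 ± 0.46. No fold is given for Dlx1, Dlx2 and Gad2, detected on at most 1 conventional array, because their control means lay below the detection limit of conventional 2. Bounds such as those of Gad1 and Glul rest on the limits averaged over the 3 conventional arrays, so a control mean under the limit of conventional 2 does not prevent them. Mbp was at least 3.20-fold and Gad1 at least 2.15-fold lower, and a Camk2a probe was at least 6.20-fold lower while a further one gave 0.08. Tubb3 and Sox11 differed by -0.16 ± 1.26 and -1.70 ± 0.67 without passing the test; both were detected on 1 conventional array, and the Tubb3 value was above 0 under the other scalings.

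By limma, 4209 of 14011 tested probes changed, 887 higher and 3322 lower, and 6996 had no overlap, against 10% over unselected probes, with the limit given above. Of the lower probes 2550 were not detected on any conventional array, and of the higher ones 19 on no control array. The median log2 difference of all tested probes was -0.81, and -0.77 to -0.03 under the other scalings. Fewer probes passed without 1 control array (1876, 1938 and 2019 without controls 1, 2 and 3), and 191 changed among probes detected on all 6 arrays, of which 97.4% were higher. In 4 lists the median, mean and test differed in sign: cell cycle, pallial and glutamatergic lineage, endothelium and pericyte, and cytoplasmic ribosomal protein. Without conventional 1, 5 lists passed instead of 3.

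Microfluidic and conventional arrays were compared directly to set the mixer against the tube at the same input. Signals of the mixer reactions were higher for Impact, a translation regulator (at least 5.37-fold; adjusted p = 5.00e-04), Slc24a5 (6.64-fold), the proteoglycan Sdc4 (5.01-fold), Ccdc92 (4.87-fold), Tmem181a (3.47-fold), Fau, which encodes a ribosomal protein (3.05-fold), the zinc transporter Slc39a1 (1.74-fold), and Spry2, an inhibitor of growth factor signalling (3.96-fold), each a lower bound. The signals that were higher in the tubes included genes that no mixer array detected: Ikbkg, of NF-kappa-B signalling (at least 42.3-fold lower in the mixer), Rrp12 (41.3-fold), Mki67 (39.8-fold), Riox2 (37.1-fold), Gapt (31.5-fold), Gskip (29.3-fold), Nfe2l1 (28.8-fold), Pdgfrb (25.9-fold) and the peptide-binding gene Crhbp (25.0-fold). The young-neuron gene Igfbpl1, detected on 1 microfluidic array, fell by 5.23 ± 0.88 and Gli3 by 2.42 ± 0.54 (SE, n = 3 and 3). No fold is given for Dcx, Dlx2, the cyclin gene Ccnd1 and somatostatin (Sst), detected on at most 1 conventional array, because their microfluidic means lay below the detection limits of conventional 2 and 3. Gapdh, Tubb3 and Sox11 had differences of 0.83 ± 0.58, 1.44 ± 1.23 and 1.81 ± 0.71 that did not pass, and Gapdh passed with median centring (2.02) and with the deposited signal values (1.16). Camk2a differed by 0.53 ± 1.08, and by -1.01 with the deposited signal values. These 4 genes were detected on 1 conventional array each.

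None of the 15 lists that could be tested shifted relative to the other tested probes: camera gave 0 calls, 0 at unadjusted p under 0.05, and adjusted p from 0.887 to 0.991. The list medians themselves were above 0 for all lists but the astrocyte list (-0.17), as was the median of all tested probes. Ribosomal protein genes rose in 5 of 32 cases (1 adjusted over the list alone), led by Rpl37a (at least 3.56-fold higher), and oxidative phosphorylation genes in 4 of 16, led by Uqcr10 (at least 2.05-fold higher). Mature neuron and synapse genes rose in 4 of 15. In 8 lists the test differed in sign from the median or mean, which were above 0 in all 8. By limma, 1953 of 7346 tested probes changed, 1638 higher and 315 lower on the microfluidic arrays, and 3601 had no overlap, against 10% over unselected probes, with the same limit. The median log2 difference of all tested probes was 1.06, and 0.27 to 1.65 under the other scalings. Of the higher probes 1125 were not detected on any conventional array, and of the 93 that changed among probes detected on all 6 arrays 3.23% were higher. Fewer passed without microfluidic 1, 2 or 3 (602, 605 and 755), more with median centring (3719), with a common spread from all 16 arrays (3160) and without the filter on dim probes (2960).

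How closely a 10 pg reaction follows the unamplified profile was also measured over all probes detected on the 3 control arrays. The Pearson r across genes with the control mean was 0.313 ± 0.0221 for the microfluidic arrays (SD, n = 3) and 0.218 ± 0.0696 for the conventional arrays (n = 3), where genes are not independent replicates. The difference of 0.0945 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow (adjusted p = 0.133 over 4 such tests). Of the probes detected on all control arrays, 61.7%, 47.4% and 64.1% were detected on the microfluidic arrays and 52.2%, 3.96% and 8.55% on the conventional arrays (exact permutation p = 0.2, adjusted p = 0.2). The 52.2% comes from the blank-spot rule used for conventional 1. With its SD filled in, an alternative chosen after seeing the data, it was 6.56%, and all microfluidic arrays lay above all conventional ones (exact permutation p = 0.1, adjusted p = 0.133), as with blank spots as the reference for all arrays (exact permutation p = 0.1). On all 3 arrays of a group, 5079 of 12227 such probes (41.5%) were detected by the mixer and 230 of 13342 (1.72%) by the tube. With blank spots as the only reference these shares were 83.4% and 21.6%. Conventional 2 alone sets much of the tube value: without it the share was 7.87%, and without conventional 3 it was 3.64%.

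Arrays of the same preparation resembled each other more than arrays of the same tissue. Mean pairwise r across genes was 0.924 among control arrays, 0.866 among explants, 0.787 among microfluidic arrays, 0.722 among single cells and 0.514 among conventional arrays. It was 0.699 between microfluidic arrays and single cells, which differ in age and tissue, but 0.195 between microfluidic and control arrays, both of adult forebrain, and 0.123 between single cells and explants, both of embryonic tissue. Control and explant arrays, both unamplified, had a mean of 0.587, and conventional arrays 0.278 with microfluidic arrays and 0.249 with cells. Pairs of arrays share members and were not tested.

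Explant arrays were compared with control arrays to describe embryonic against adult tissue without amplification. Genes of the embryonic eminence, of young neurons and of dividing cells rose. The CGE and eminence identity list rose in 10 of 20 members and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 4.37e-04), with the interneuron transcription factor genes Dlx5 (at least 19.2-fold higher), Nr2f2 (4.26 ± 0.27 log2 units higher; SE, n = 3 and 3), Dlx1 (3.52 ± 0.27) and Dlx2 (1.22 ± 0.24). Immature and migrating neuron genes rose in 13 of 26 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 4.01e-07), among them Nrep (at least 42.3-fold higher), Sox11 (at least 16.9-fold), Cd24a (5.28 ± 0.30), Marcksl1 (4.68 ± 0.25), Dcx (3.69 ± 0.21) and Tubb3 (2.20 ± 0.24). Neural progenitor genes rose in 9 of 15 and fell in 0 (13 and 0 adjusted over the list alone; adjusted p = 6.21e-07), led by the radial glia gene Fabp7 (4.97 ± 0.24), Ccnd2 (4.41 ± 0.26) and Sox3 (3.51 ± 0.23). In the cell cycle list 14 of 20 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 1.99e-08), with Ccnb1 and Mcm7 at least 19.5-fold and 16.4-fold higher, Hmgb2 4.21 ± 0.24 and Mki67 1.83 ± 0.24 log2 units higher.

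Cytoplasmic ribosomal protein genes rose in 51 of 64 cases and fell in 1 (53 and 1 adjusted over the list alone; adjusted p = 1.81e-21), with Rps27a, Rps27l and Rpl12 higher by 3.95, 3.65 and 3.23 log2 units. Replication-dependent histone genes rose in 9 of 15 and fell in 0 (9 and 0 adjusted over the list alone; adjusted p = 3.31e-06, and adjusted p = 0.0524 with an estimated correlation, 3.50e-08 to 0.0659 over the alternatives), H1f5 at least 30.9-fold and H2ac8 by 5.38 ± 0.29. Oxidative phosphorylation genes rose in 18 of 63 and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 4.85e-05), led by Cox7a2 (3.10 ± 0.30). Housekeeping genes rose in 7 of 18, including Eef2 and Tpt1, and fell in 3, including B2m, which was at least 1.59-fold lower (8 and 3 adjusted over the list alone; adjusted p = 0.0483, and adjusted p = 0.260 with an estimated correlation). Of 6 erythroid genes 2 rose, the embryonic globin gene Hbb-y by 3.45 ± 0.22 and Hba-a1 by 2.96 ± 0.46, and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.0483, and adjusted p = 0.143 with an estimated correlation).

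Genes of mature neurons fell on the explant arrays. Mature neuron and synapse genes fell in 33 of 34 cases and rose in 0 (33 and 0 adjusted over the list alone; adjusted p = 1.49e-12), with Sncb at least 21.4-fold, Thy1 at least 20.1-fold, Camk2a at least 17.2-fold, the neuropeptide gene Cck at least 14.2-fold, Snap25 at least 5.16-fold and Penk at least 4.11-fold lower; a further Camk2a probe gave -0.08. Oligodendrocyte and myelin genes fell in 11 of 15 and rose in 0 (11 and 0 adjusted over the list alone; adjusted p = 4.85e-05, and adjusted p = 0.0612 with an estimated correlation, 6.27e-06 to 0.0612 over the alternatives), with Mbp and Mobp at least 12.6-fold and 2.21-fold lower. Astrocyte genes fell in 10 of 17 and rose in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.00626, and adjusted p = 0.142 with an estimated correlation, 1.42e-04 to 0.722 over the alternatives), among them Slc1a2 (at least 3.83-fold lower) and the water channel Aqp4 (2.93-fold). The lists that did not pass were pallial and glutamatergic lineage (1 rose and 6 of 10 fell; adjusted p = 0.0921), microglia and macrophage (0 and 5 of 10; 0.0743), endothelium and pericyte (0 and 4 of 11; 0.0761) and immediate early and stress response (0 and 3 of 10; 0.614). Among their members the extracellular matrix gene Reln was at least 1.87-fold, the activity-regulated gene Arc at least 2.82-fold and the complement gene C1qc at least 1.34-fold lower. Gad1 fell by 0.82 ± 0.27, while Gad2 differed by 1.31 ± 0.51 without passing. Gapdh was saturated on all control arrays, so its difference of -0.11 ± 0.22, which did not pass, does not exclude a larger fall.

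**Figure D2:**
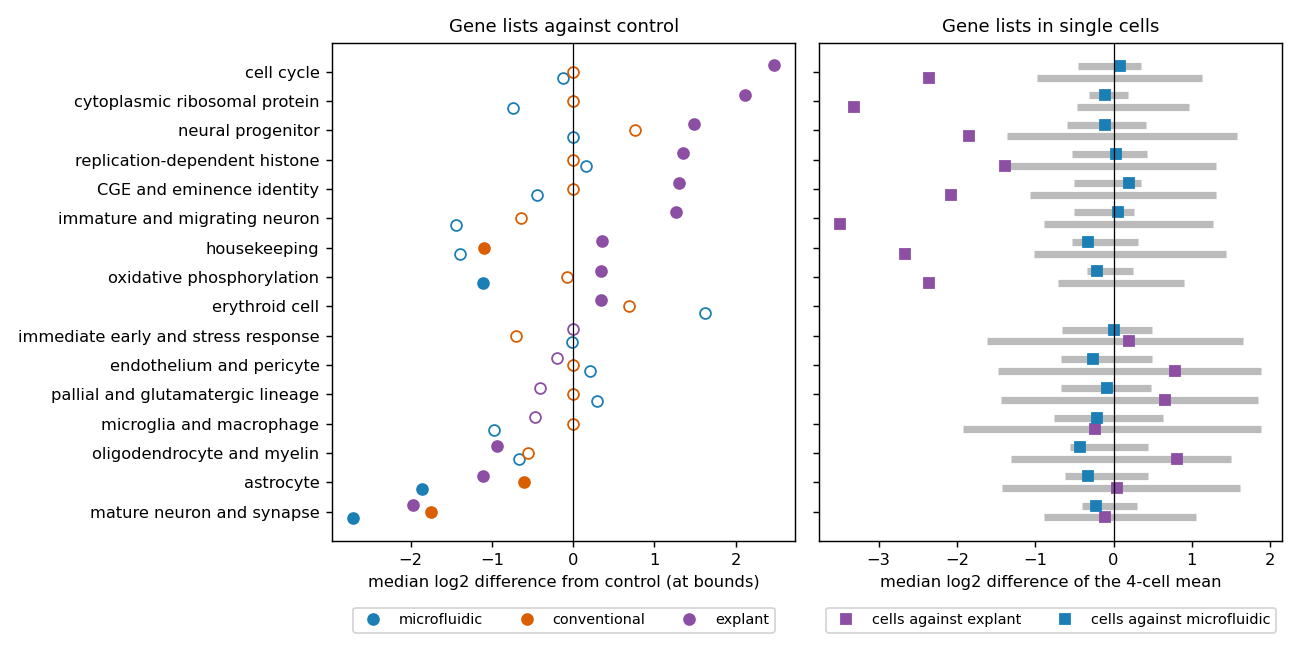
Left, median log2 difference from the control arrays of the tested members of each gene list, with genes undetected in 1 group placed at their detection bound; filled circles passed camera with the preset correlation, and mature neuron and synapse genes are filled in all 3 groups. Right, median log2 difference of the mean of the 4 cells from explant and from microfluidic arrays (squares), with grey bars for the central 95% of 10000 random lists; against explants the immature neuron and ribosomal lists lie at -3.49 and -3.31.

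The genes that the naming rule picked for the largest fitted rises were detected on no control array: Trex1, an exonuclease (at least 74.7-fold higher), the serotonin receptor gene Htr6 (72.2-fold), Rbm12b2 (69.9-fold), Speer4a (64.6-fold), the sorting nexin Snx27 (64.1-fold), the keratin Krt76 (63.9-fold), Lrrd1 (63.3-fold) and the homeobox gene Tlx1 (42.1-fold). They belong to 94 such probes, which also include those of Nrep, H1f5, Ccnb1, Dlx5 and Mcm7 named above. Of the 94, 46 had a saturated spot marked as bad by the scanner software on at least 1 explant array. The other large falls were in Faim2 (at least 23.5-fold), Zfp365 (18.9-fold), the paranodal adhesion gene Cntnap1 (18.2-fold), the proton channel Hvcn1 (15.4-fold) and the cytoskeletal linker Macf1 (11.3-fold), of which a further probe rose by 3.36. By limma, 5898 of 13885 tested probes changed, 2162 higher and 3736 lower, and 8011 had no overlap, against 10% over unselected probes, with the same limit. Of the lower probes 2714 were not detected on any explant array. The median log2 difference of all tested probes was -0.30, and -0.44 to -0.18 under the other scalings. Age, strain, region, labelling chemistry and slide print series differ between these groups together, 1829 probes passed with a common spread from all 16 arrays, and 1523 among probes detected on all 6 arrays, of which 76.2% were higher. The housekeeping call was lost under 7 of 15 alternatives (adjusted p 0.00717 to 0.722), the erythroid call under 8 of 14 (0.0209 to 0.143), and the oxidative phosphorylation call with the deposited signal values (2.05e-05 to 0.244 over 15). Among probes detected on all 6 arrays the CGE, immature neuron, astrocyte, oxidative phosphorylation, histone and housekeeping lists did not pass either, and too few oligodendrocyte and erythroid genes were left to test.

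Single cells were set beside explants, which hold the same tissue if the CGE label is right, to see which of its transcripts the cells carried. No label names the animal of a cell, so the 4 cells count as 1 sample and no test was made. Young-neuron, ribosomal and housekeeping transcripts gave lower signals in the cells. The immature neuron list had a median log2 difference of -3.49 (-3.30 with undetected genes at their bound), the ribosomal list -3.31 (-3.18), the housekeeping list -2.67 (-2.67), the oxidative phosphorylation list -2.36 (-1.56), the cell cycle list -2.36 (-1.57) and the CGE list -2.07 (-1.82), each lower than at least 99.9% of 10000 random lists of like mean expression. In explants against controls the same lists lay at percentiles 98.9 to 100 of random lists. The random lists were thus not matched on brightness in explants, which by itself favours a low percentile here. Against microfluidic arrays the same lists lay between percentiles 12.1 and 87.2. The progenitor list had -1.84 (percentile 0.370) and the histone list -1.39 (percentile 2.17). The remaining lists lay between percentiles 35.8 and 83.9, with medians from -0.24 for microglia to 0.81 for oligodendrocytes. With adult RNA, microfluidic minus control medians were -1.76 for immature neuron, -1.49 for housekeeping and -1.12 for oxidative phosphorylation genes. They were -0.93 for CGE and -0.74 for ribosomal genes, but -0.0016 for cell cycle, 0.14 for progenitor and 0.16 for histone genes. Where a list was also lower with adult RNA, its lower signal alone does not show that the cells lack the transcripts. Nor is this shown for the cell cycle, progenitor and histone lists. These were brighter on explant than on control arrays, so adult RNA does not test amplification at that level. Fabp7 was at least 23.7-fold, the chaperone gene Hsp90ab1 at least 23.7-fold, the elongation factor gene Eef2 at least 25.9-fold, Rpl18 at least 26.0-fold, Rpl13 at least 24.8-fold, Cdk4 at least 21.1-fold and Mki67 at least 12-fold lower in the cells. Dlx1, Dlx5 and Dlx2 had differences of -4.93, -3.22 and -2.13, Gad2 and Gad1 of -3.14 and -2.67, Dcx of -2.12, Gapdh of -1.53 (0.01 with median centring) and Tubb3 of -0.09. Of these, Dlx1, Dlx5, Gad1 and Gad2 were detected in at most 2 cells each. No fold is given for Sox11, saturated on all explant arrays and in cell 1. With no background correction, median centring or the deposited signal values, 7 list medians were smaller in size: -3.06 to -2.75 for immature neuron, -2.83 to -2.73 for ribosomal, -2.13 to -1.70 for housekeeping, -2.00 to -1.64 for oxidative phosphorylation, -1.77 to -1.55 for cell cycle, -1.65 to -1.40 for CGE and -1.61 to -0.96 for progenitor genes. Others spread to both sides or lay lower, with -1.63 to -0.96 for histone, -0.95 to -0.14 for microglia, -0.71 to 0.52 for mature neuron and -0.83 to -0.06 for astrocyte genes.

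Several genes of other cell types were brighter in all 4 cells than in the explants. The glutamatergic transporter Slc17a7 was at least 13.9-fold, the oligodendrocyte transcription factor Sox10 at least 9.10-fold, the endothelial gene Vwf at least 6.17-fold and the microglial receptor Csf1r at least 2.45-fold higher, and Cdk1 differed by 3.81. With adult RNA, too, the mean of the microfluidic arrays was higher than that of the unamplified controls for Slc17a7 (by 2.25 log2 units), Sox10 (1.73), Vwf (2.84) and Cdk1 (0.71), though not for Csf1r (-1.15), so these signals alone do not show that the cells express the genes. Mbp was detected on no explant array and in 2 cells, so no difference is given. The highest fitted differences belonged to Hk2, a hexokinase (at least 18-fold), Macf1 (15.1-fold), Rbm10 (14.1-fold), Ccbe1 (13-fold), Nxf7 (11.3-fold), Akr1b7 (10.7-fold), Lcn4 (9.14-fold) and the zinc transporter Slc30a6 (5.28-fold). The lowest, next to Fabp7, were Rmrp (at least 40.0-fold lower), Rbm27 (39.7-fold), Pirt (39.3-fold), Wwc1 (35.7-fold), Nlrp4f (35.6-fold), Lrrd1 (31.9-fold) and Snx27 (31.1-fold). The last 6 belong to the 94 probes detected on explant but on no control arrays, which may in part be faulty spots. All 4 cells lay above all 3 explants in 2383 of the 4127 probes detected in every cell, and below them in 1713 of the 2736 detected in every explant, where chance gives 2.86% each way over unselected probes. Selecting probes by detection in 1 group raises that share, so the counts are descriptions. Without cell 4 the first count was 3838, with fewer cells to satisfy.

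Single cells were also set beside the microfluidic arrays, which held adult RNA taken through the mixer and the same number of PCR cycles, with a shorter reverse transcription, again without a test. The cytoskeletal regulator Stmn1, abundant in young neurons, was higher in the cells by 3.64 log2 units, Cd24a by 2.00 and Sox11 by 1.79, while the myelin junction gene Cldn11 was at least 6.83-fold lower and Gja1, saturated on all microfluidic arrays, was lower by at least 3.12 log2 units. Further genes on the high side were Hspa12a (at least 18.3-fold), the chaperonin Cct8 (9.33-fold), Smim18 (4.77-fold), the autophagy kinase Ulk2 (4.75-fold), Pitpna (3.71 log2 units), Armcx4 (3.65) and Man2b2 (3.22). Those on the low side were Scn2b (at least 38.1-fold lower), Pdcd4 (29.5-fold), Canx, a chaperone (24.5-fold), Eif1b (24.4-fold), Spry2 (21-fold), B3galt1 (20.8-fold), and Sdc4 and Impact, which were saturated on all microfluidic arrays and detected in 1 cell each, so that no fold is given. The CGE list had a median difference of 0.20 (0.04 with undetected genes at their bound; percentile 87.2), with 0.11 and 0.28 in cells 1 and 2 and -0.31 and -0.49 in cells 3 and 4, and the oligodendrocyte list -0.42 (-0.19; percentile 6.29), and the other lists lay between them. In cell 2 alone, ribosomal genes had a median of -0.73, below all random lists. Of the other anchor genes, Gapdh differed by -0.07, Snap25 by -0.02, Dlx2 by 0.08, Dlx5 by 0.17, Camk2a by 0.40, Dcx by -0.41, Gad1 by -0.73, Tubb3 by 0.83, Mbp by 0.86 and Gad2 by 0.95. Dlx1 is given no difference, since cell 4, the only cell to detect it, had 12.24 against a microfluidic mean of 12.37. Mki67 was detected in neither group, and Dlx5, Gad1, Gad2, Mbp and Snap25 in at most 2 cells each. All 4 cells lay above all 3 microfluidic arrays in 446 of 4127 probes and below them in 780 of the 6584 detected on every microfluidic array, with the same limit on reading them against the 2.86% of chance. Without cell 2 and without cell 4 the first count was 973 and 1001.

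To see whether amplified arrays carry the embryonic-adult difference of the unamplified ones, the difference between explants and controls was correlated with that between cells and microfluidic arrays, which share no array. Across 13716 probes Pearson r was 0.0728 (jackknife SE 0.0661) and Spearman rho 0.0853. Of 4243 probes that changed over 2-fold between explant and control, 56.3% differed in the same direction on the amplified arrays, against 54.2% of all 13716. Examples with the same direction were Cd24a and Sox11. Dcx had the opposite direction, with cells 3 and 4 below and cells 1 and 2 above the microfluidic mean. By contrast, the difference between amplified and unamplified adult RNA correlated with that between cells and explants at r = 0.708 (rho 0.714), and 77.6% of probes had the same sign. Genes are not independent, and both relations are descriptions.

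**Figure D3:**
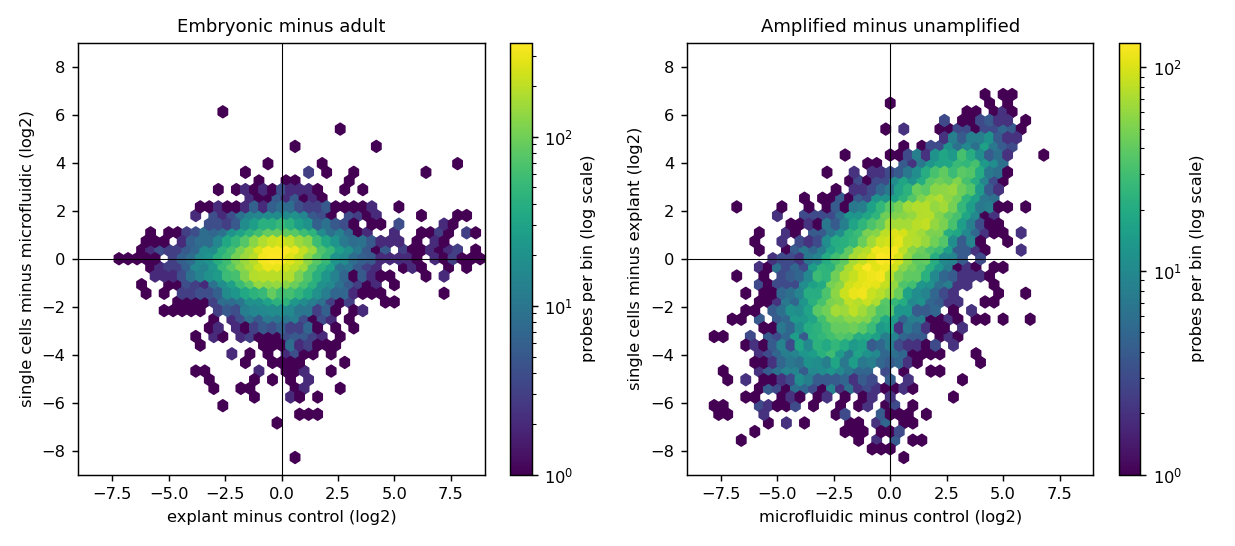
Log2 differences of 13716 probes, coloured by probes per bin on a log scale. Left, embryonic minus adult on amplified arrays (y) against unamplified arrays (x), r = 0.0728; right, amplified minus unamplified in embryonic (y) against adult samples (x), r = 0.708.

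For each cell, genes were also picked for the largest excess over the other cells, a choice that by itself finds signals peculiar to 1 array. Tubb3, Dcx, Sox11, Stmn1 and Dlx2 were detected in all 4 cells, with Tubb3 at log2 intensities of 15.39, 15.30, 14.07 and 15.42 and Dlx2 at 12.58, 14.64, 12.40 and 13.97. Signals most particular to cell 1 were Map3k1, a stress kinase (15.94), Sdr42e1 (15.97), Plscr2 (14.94) and Pdzd8 (14.97). Cell 2 stood out for Nvl (15.94), Zbtb39 (15.93), Inpp5f (14.67) and the transcription factor Tbx2 (14.57), cell 3 for the DNA repair gene Aplf (15.59), Birc6 (15.30), Anxa1 (14.38) and the GABA transaminase Abat (14.33). In cell 4 these were Meig1 (15.98), the odorant receptor Olfr661 (15.96), the histone mRNA-binding gene Slbp (15.88) and Zfp367 (15.17). None of these 16 genes was detected in another cell by the probe given; further probes of Pdzd8 in cell 1 and Slbp in cell 4 gave 9.21 and 10.06. Among the 16, Birc6 and Zfp367 had the highest means on the microfluidic arrays of adult RNA (15.15 and 13.21). Cells are single measurements, so the spread of repeated measurements of 1 cell is unknown. A signal in 1 cell alone thus does not show a transcript particular to that cell.

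**Figure D4:**
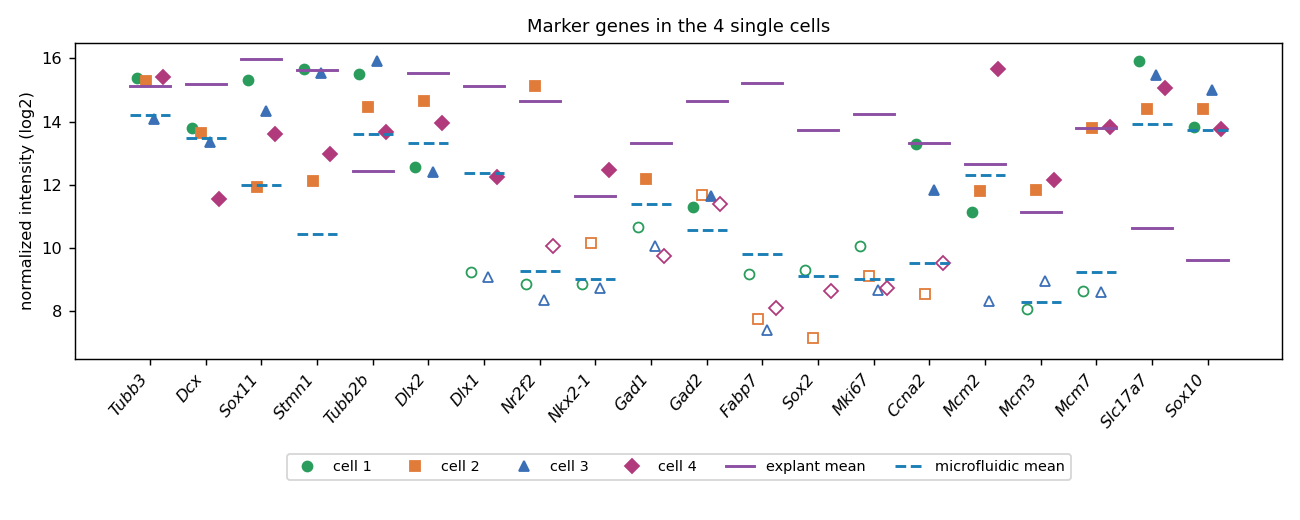
Normalized log2 intensity (y) of marker genes (x) in each of the 4 cells; filled symbols were detected over local background, open symbols were not. Lines are the means of the explant (solid) and microfluidic (dashed) arrays; Tubb3, Dcx, Sox11, Stmn1 and Dlx2 are detected in all 4 cells and Fabp7 and Mki67 in none.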

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

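The test of embryonic lists among explant-only probes was chosen only after the result was seen, and the other tests were written down before it. Dixon's ratio, the gap of the most distant cell from the nearest other divided by the whole range, was taken for 122 values over the 4 cells, and 21 were over the 95% limit. Chance puts about 1 in 20 over it, and 13 of the 21 are genes named for their excess in 1 cell, which selects for a high ratio.

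Among genes not chosen for an excess, Tubb3 was lower in cell 3 than in the other cells (ratio 0.907), and Tyms (0.918) and Gja1 (0.835) were higher in cell 4. Cell 4 was scanned in a session of its own, so its differences from the other cells cannot be told apart from scan session. Of the genes with the lowest signals against explants, Rbm27 was highest in cell 1 (0.865), Rmrp lowest in cell 2 (0.853) and Rpl18 lowest in cell 1 (0.895), all at levels below detection. The median of the pallial list against explants was -0.02 in cell 4 and 0.83 to 0.92 in the others (0.900), and that of the endothelium list against microfluidic arrays was -1.06 in cell 4 and -0.15 to 0.01 in the others (0.854). For genes chosen for 1 cell the ratios were 0.947 for Plscr2 and 0.844 for Pdzd8 in cell 1, and 0.899 for Nvl, 0.935 for Zbtb39 and 0.908 for Inpp5f in cell 2. They were 0.982 for Aplf, 0.935 for Anxa1, 0.888 for Birc6 and 0.927 for Abat in cell 3, and 0.955 for Olfr661, 0.942 for Meig1, 0.864 for Slbp and 0.928 for Zfp367 in cell 4.

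Some genes and lists went opposite ways on every array of the groups set side by side; these differences were not tested. Oxidative phosphorylation genes had medians of 0.30 to 0.40 in explants against controls and -0.33 to -0.08 in cells against microfluidic arrays, a gap of -0.55, and housekeeping genes 0.19 to 0.94 and -0.27 to -0.17, a gap of -0.85. Camk2a was lower in every explant than in controls and higher in every cell than in microfluidic arrays, a gap of 4.5 that rests on a probe saturated on all control arrays. Mbp was lower in amplified than in unamplified adult RNA and higher in cells than in explants, a gap of 6.83; Mbp was detected on no explant array and in 2 cells, so this gap rests in part on values at background. Dcx went the other way, by -4.10. Buffer spots, which hold no probe, had median net intensities of at least 101.5 on the explant arrays and at most 11.8 on the control arrays.

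The first pattern weighed is that amplified and unamplified arrays differed in the same genes in adult RNA and in embryonic cells (r = 0.708). Background correction and quantile normalization do not account for it, since r was at least 0.704 under 3 other processings, and neither do saturated or dim probes, since r was 0.537 (0.513 to 0.557 with an array left out) over 295 probes detected on all 13 arrays and saturated on none. Template-switching amplification is a candidate explanation that stays open. The tube reactions, amplified the same way but not in the mixer, differed from controls with r = 0.370 (0.321 to 0.403) against the same embryonic difference. Control and explant arrays, each subtracted on 1 side, had a mean pairwise r of 0.587, and conventional arrays and cells 0.249. A positive r can therefore come from the unamplified arrays alone, so it does not decide the question. Labelling chemistry and scan session also differ between amplified and unamplified arrays and stay open. No biological explanation was tested.

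The second pattern is the 94 probes bright on explant arrays and detected on no control array. A fault of neighbouring spots may account for part of them, since 10.6% had another of the set in a neighbouring spot, where random sets gave a median of 2.13% and an upper limit of their central 95% of 8.51%. Embryonic expression stays open as an explanation of part of them. Of the 94, 6 were members of the 4 embryonic lists, where random draws gave a median of 0 and an upper limit of 1. The set was chosen for being higher on explants, where these lists rose, whereas the draws were not. That excess was therefore likely beforehand and does not decide the question. None of the 6 was among the 43 probes saturated on all explant arrays measured. Without saturated spots marked as bad by the scanner software 51.1% were still called, but leaving out those spots partly fixes that outcome, so these spots cannot be told apart from true signal. The explant arrays are also the only ones with a header from their slide print series, which cannot be told apart from the group. Of the 94, 66 were detected in no cell and 5 in all 4 cells.

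The third pattern is the genes bright in all 3 tube reactions and detected on no control array, which holds for 19 tested probes. The overlaps were taken over the 100 brightest of 6234 probes detected on no control array, whether or not every tube detected them. Of the 100 brightest of the tubes 3 were among the 100 brightest of the mixer, where chance gives 1.6. The brightest 100 overlapped between pairs of tube arrays by 33.3 probes on average (24 to 41). Loss and amplification of single molecules, independent in each tube, was predicted to give under 10. Over 50 was written down beforehand as the limit that would exclude it. Most of the probes in each 100 were not detected in every tube, so neither overlap can decide the cause of this pattern. What the tubes share stays open. No biological explanation was tested, since tube and control reactions held the same kind of RNA.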

How the results depend on the processing

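Alternatives with probes detected in both groups, without saturated spots marked as bad, or with a filled background SD, and most list alternatives, were tests chosen after the data were seen; the others were planned. A sign change was counted as a reversal only where a value passed its threshold or exceeded the spread of its group. In no result below was the cause of a change tested, except that fewer probes or arrays were used where that is said.

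An intensity trend, run for probe counts and named genes, left the counts within 1.5 times their main value. It kept all 157 named gene values on their side of the threshold. The replicate block, quantile normalization within 2 groups, a filled background SD and the omission of saturated spots marked as bad left every count of probes and lists within 1.5 times its main value. Restricting to probes detected in both groups, which tests fewer probes, gave 2898 changed probes for microfluidic against control, 191 for conventional against control, 93 for microfluidic against conventional and 1523 for explant against control, with 4 lists in the last. Without the dim-probe filter these were 6940 for conventional against control and 2960 for microfluidic against conventional, with 5 lists for microfluidic and 7 for conventional against control. With the deposited signal values, conventional against control gave 8267 probes and 6 lists. Median centring gave 3719 probes for microfluidic against conventional, and a common spread from all 16 arrays 3160, and 1829 for explant against control. With an estimated correlation 0 lists passed for microfluidic and for conventional against control and 7 for explant against control. No list call changed direction under any alternative run. Of 157 named gene values in the tested comparisons, 151 kept direction and side of the threshold with median centring and 157 without background correction, and 143 did with the deposited signal values, where 7 did not and the rest had no fitted value.

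With each array left out, which uses fewer arrays, probes changed ranged from 1876 to 5959 for conventional against control, 602 to 2575 for microfluidic against conventional, 7452 to 9113 for microfluidic against control and 4183 to 5961 for explant against control. Lists ranged from 3 to 5 for conventional, 2 to 3 for microfluidic and 10 to 12 for explant against control. The r of microfluidic arrays with control was 0.418 over all probes and 0.290 by Spearman. Mean r within groups ranged from 0.906 to 0.947 for control, 0.774 to 0.795 for microfluidic, 0.444 to 0.615 for conventional and 0.827 to 0.894 for explant arrays, and for microfluidic arrays it was 0.799 without background correction, 0.798 with median centring and 0.800 by Spearman. Control-detected probes found on all microfluidic arrays were 54.2% at background plus 1 SD, 83.4% by blank spots and 40.7% to 52.8% with an array left out, against 1.65% to 7.87% for conventional. Cells above all explants numbered 2496 to 3838 without a cell and below them 1830 to 1915; against microfluidic arrays these were 553 to 1001 and 952 to 1149.

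Of 30 list medians in cells, 10 moved by more than their spread with median centring, 7 without background correction and 12 with the deposited signal values, and of the genes named in cells 26, 43 and 35 did. With median centring, Dlx2 in microfluidic against control was 0.25, and in cells against explant Erbb4 was 0.71 and Gapdh 0.0140. With the deposited signal values, Camk2a in microfluidic against conventional was -1.01. The immature neuron median of cells against microfluidic arrays was -0.0224 with median centring and ranged from -0.0849 (without cell 2) to 0.171 (without cell 3) with a cell left out, and the mature neuron median from -0.334 (without cell 2) to 0.00981 (without cell 3). Dim signal limits the comparisons with control, where 2727 lower probes for microfluidic, 2550 for conventional and 2714 for explant arrays were known only by a bound. Too few list members were left to test the lists of microfluidic against conventional among probes detected in both groups, and a block for scan session could not be fitted.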

Other observations

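The values below belong to single cells or single sets of arrays, the cell markers were picked from the lists after their values were seen, and counts over other splits of the arrays were planned.

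Cell cycle and regional genes varied between the 4 cells. Transcripts of the replication helicase genes Mcm7 and Mcm3 were detected in cells 2 and 4, Mcm7 at log2 intensities of 13.81 and 13.82 and Mcm3 at 11.84 and 12.14. Cell 4 had Mcm2 at 15.68, the thymidylate synthase gene Tyms at 14.88 and the ribonucleotide reductase gene Rrm1 at 14.55. Slbp was bright there by 1 probe, while a further probe lay below the lowest detected intensity of that array. No other cell shares the scan session of cell 4, so its values cannot be told apart from that session. The mitotic cyclin gene Ccna2 was detected in cells 1 and 3 (13.30 and 11.83), while Mki67 was detected in no cell. Nr2f2, a transcription factor gene of the CGE, was detected in cell 2 alone (15.12), and Nkx2-1, which marks the medial eminence, in cell 4 alone (12.47), as was Dlx1 (12.24), which had no value in cell 2. The interneuron receptor genes Erbb4 and Cxcr4 were detected in all 4 cells. A single cell was measured 1 time each, so these values carry no error.

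Each cell detected part of every list with members on the array. Of the CGE list, 16 of 25 measured members were detected in cell 1, 17 of 24 in cell 2, 13 of 23 in cell 3 and 7 of 24 in cell 4. Immature neuron genes were detected in 13 of 25, 18 of 27, 14 of 27 and 7 of 26 cases, and cell cycle genes in 16 of 32, 18 of 32, 12 of 32 and 11 of 31. Lists of cell types other than neurons were detected too: oligodendrocyte genes in 10 of 17, 10 of 18, 8 of 18 and 4 of 19 cases, astrocyte genes in 8 of 17, 10 of 18, 8 of 16 and 7 of 17, and microglial genes in 3 of 14, 5 of 12, 1 of 15 and 1 of 14. Endothelium and pericyte genes were detected in 7 of 13, 11 of 14, 9 of 13 and 4 of 14 cases. For erythroid genes these were 6 of 7, 4 of 7, 2 of 7 and 4 of 6. Pallial and glutamatergic genes were detected in 62.5%, 75%, 64.3% and 43.8% of cases, beside 64%, 70.8%, 56.5% and 29.2% of the CGE list. Detection shares alone thus do not set the CGE list apart from the pallial list. The oligodendrocyte gene Ermn reached 15.02 in cell 3. The share of all probes detected was 44.7%, 52.5%, 35.5% and 26.5%, beside 58.8%, 55.6%, 44.4% and 21.1% of the oligodendrocyte list and lower shares of the microglial list, so detection of such genes alone does not show another cell type.

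With 3 arrays against 3 there are 10 splits, the real one included, too few for a share under 0.05. For microfluidic against control, 1 of the 10 splits gave as many changed probes as the real one (8932; highest other 0) and 4 gave as many lists (3; highest other 3). For conventional against control these were 1 split for probes (4209; highest other 0) and 1 for lists (3; highest other 2). Between microfluidic and conventional arrays they were 1 for probes (1953; highest other 0) and 10 for lists (0; highest other 0). For explant against control they were 1 for probes (5898, highest other 0) and 1 for lists (12, highest other 10 and lowest 5). Splits that mixed explant and control arrays thus also shifted at least 5 lists.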
